A study of Bos taurus with 4 samples.

How the data were processed

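Gene expression was measured in Holstein (Bos taurus) embryos on 4 dual-colour microarrays. Per the labels' protocols, superovulated cows were sorted by the blood concentration of beta-hydroxybutyrate (BHB), a ketone body that accumulates in negative energy balance: under 0.9 mmol/l in the low group and over 0.9 mmol/l in the high group. They were inseminated with sexed semen, and morulas and blastocysts were recovered 7 days after oestrus. Total RNA was amplified with the RiboAmp HS Plus kit, labelled with the Universal Linkage System and hybridised to Agilent slides, per the labels. Each array held 1 RNA of the high group and 1 of the low group. On arrays 1 and 2 the high group was in Cy5 and the low group in Cy3, and on arrays 3 and 4 the dyes were exchanged. The labels number the arrays as biological replicates 1 to 4 and do not say whether a replicate was 1 cow or a pool, so that p-values measure the spread between these arrays. The titles repeat the numbers 1 and 2 on arrays 3 and 4. By the titles alone arrays 1 and 3, and 2 and 4, could have carried the same RNA with dyes exchanged. That reading was run as an alternative, and the correlations between arrays are set against it below.

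The deposited scanner files hold the intensity of each spot and of its local background in both channels, per the file headers, with no normalization. The scanner software is not given in the sources used here. The authors also deposited log2 ratios per array, in a table of Cy5 over Cy3 and in a table per sample, and the submitters' processing notes name limma without a step. Set against the scanner values, the deposited log2 values of the per-sample table were log2 ratios already turned to high over low BHB, centred near 0 (array medians 0.014, 0.00096, 0.0047 and 0.017). They lay closest to median spot intensities minus local background after loess (r = 0.93 to 0.98 across probes). The other table held the same values up to sign, with differences of at most 3.6e-05, and was not run apart from it. Which background step the authors took is not given in the sources used here.

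The ratios reported here were computed from the scanner files. Median spot and median background intensities were used, a choice made after these columns were found to lie closest to the deposited ratios. Background was corrected with normexp (offset 50), and each array was normalized with loess (span 0.3), with control spots and spots that the scanner software had set aside (95 to 114 per array) at weight 0. Log2 ratios were turned to high over low BHB on every array. Spots set aside were left out of the fit. A probe counted as above background where its foreground exceeded the mean plus 2 SD of the 153 negative control spots in that channel. This held for 32.4%, 36.7%, 35.2% and 20.1% of probes in the high BHB channel of arrays 1 to 4, and for 48.2%, 40.4%, 32.4% and 36.5% in the low BHB channel. On array 4, 1 negative control spot at 2060 intensity units, with the next at 335, raised the Cy3 threshold to 571.5, against 310.5 from the median plus 2 MAD. That channel held the high BHB group, so this spot lowered the number of probes above background in that group alone: on array 4 it was 20.1%, and 39.7% with the median plus 2 MAD. After normexp the negative control spots had median intensities of 128 to 604 units. In Cy3 of arrays 1 and 4 and in Cy5 of array 4 normexp added signal: the control level was 257, 217 and 84 units after local background alone, and 442, 604 and 327 after normexp. At most 6 spots per channel, set aside by the scanner software and with local backgrounds far above their foreground, had put the fitted background mean below 0 there. This was found after the results were known, and the correction was kept as it was. With normexp fitted without the spots set aside, run as an added alternative, the control level was 115 to 248 units. The SD of the log2 ratios of tested probes then went from 0.739 to 0.857 on array 1 and from 0.449 to 0.623 on array 4. On array 2 it went from 0.406 to 0.441. The spread of the ratios reported here was thus compressed on these arrays, least on array 2. Mean log2 ratios of single genes went both ways with that fit. FN1 went from 0.71 to 0.43, and KSR1 from 0.90 to 1.18. Spots set aside had also lowered the fitted background mean in Cy5 of array 1 (28.8, against 100 without them) and in Cy3 of array 2 (69.6, against 179).

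Of 43794 probes, 15038 were above background in the channel of at least 1 group on at least 3 of 4 arrays and were tested. Gene names came from the platform's annotation. It paired 21790 probes with 1 symbol each, none with several, and 22004 probes had no symbol. Symbols were updated through the RefSeq gene table of assembly ARS-UCD2.0, used for names alone: 20068 probes matched a current symbol, 1644 a synonym and 78 neither. A gene was represented by its brightest tested probe (7281 genes from 9008 named probes). Probe sequences and a genome were not used here, so that GC content, probe position and transcript length were not examined.

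The comparison was the mean log2 ratio against 0 over the 4 arrays, fitted with limma (version 3.58.1, R 4.3.3; lmFit and eBayes, no dye term, 6.6 total degrees of freedom) and adjusted by the Benjamini-Hochberg method over all tested probes. An adjusted p under 0.05 was the threshold. An exploratory threshold, uncorrected for the number of probes, was an unadjusted p under 0.05 with a 1.5-fold difference. The 30 gene lists were tested with limma's camera (preset correlation 0.01) where at least 5 members were measured, adjusted over the 24 lists tested, with camera at an estimated correlation and fry beside it. Camera compares a list with the other genes, so its direction is relative to them. A dye effect was fitted as a second term. Within-array pairing of the 2 groups was kept in the ratio itself. A probe dim in one group on all 4 arrays has only a bound there. The bound is the brighter group's mean over the dimmer group's mean of, per array, the higher of the lowest signal above background and the probe's own. It was taken from channel values after loess and Aquantile. For the named gene concerned, ZAR1L, its own signal was the higher on each array, so that the bound equals the fitted ratio.

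The design, the gene lists, the alternatives and the rule for naming genes were set before the data were examined. The real arrays had been analysed before the simulation described below was written. The rule took 12 genes per direction: those past the threshold first, then, since none passed, those of the smallest unadjusted p among genes of at least 1.5-fold and 1 direction on all 4 arrays. It added the 3 measured members of each list with the largest ratios in size, and 26 genes of ketone metabolism, chromatin and lineage. Of these 26, 15 were tested and 7 had probes that did not pass the filter. HCAR2, TET1, IFNT2 and GATA6 were not analysed here. In all 117 genes came under the rule. Of these, 18 had several tested probes, and in 4 (PDK1, CYP51A1, GRB10 and CXCL2) the probes differed in sign.

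Alternatives changed 1 choice at a time: no background correction, normexp offset 0, median centring in place of loess, Aquantile, no filter or a stricter filter on dim probes, a dye term, the deposited log2 values, no pairing within arrays, title numbers as technical dye swaps, eBayes with trend and robust, and leaving out each array. Loess on the tested probes alone, a threshold of median plus 2 MAD and normexp fitted without the spots set aside were added after seeing the data. The steps were tested on simulated intensities for 4 arrays with the real probes' brightness and spread, a dye curve and 200 of 15038 probes changed. The first 2 forms of the simulation returned too large ratios because their additive level did not match that of the arrays; the simulation was revised until it did, and the analysis steps were left as they were. One simulation was run in the final form. It held no spots with local backgrounds far above their foreground, so the fault of the normexp fit described above was not simulated. The simulated noise was drawn for each probe on its own, so that correlation between probes was not simulated, in the list step either. Recovery, false calls and ratios on the real arrays may therefore differ from those given here. At an adjusted p under 0.05, 4% of the probes changed 1.5-fold were recovered, 18% of those changed 2-fold, 66% at 4-fold and 88% at 8-fold, against 4 calls among 14753 unchanged probes. The remaining 85 probes, of ribosomal proteins, were lowered together by a log2 of 0.3 to test the list step. At the exploratory threshold 128 of the unchanged probes passed. Simulated changes of 2-fold came out at a median log2 of 0.61 in place of 1, and at 0.81 among brighter probes. The number of arrays limits the precision: the median standard error of a log2 ratio was 0.18.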

Results

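The study asked how embryos respond to raised BHB in the blood of the mother. Total RNA of morulas and blastocysts from cows with high or low BHB was compared on 4 arrays, each with 1 RNA per group, with dyes exchanged on arrays 3 and 4. Values below are log2 ratios of high over low BHB, as mean ± SD over the 4 arrays (n = 4). Spot intensities had medians of 213 to 421 units in Cy5 and 290 to 612 in Cy3. The SD of the log2 ratios of tested probes was 0.74, 0.41, 0.53 and 0.45 on arrays 1 to 4.

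The arrays resembled each other weakly. Across tested probes, which are not independent replicates, Pearson's r between turned ratios was 0.50 for arrays 1 and 4. It lay between 0.21 and 0.25 for arrays 1 and 2, 2 and 3, 2 and 4, and 3 and 4, and was 0.09 for arrays 1 and 3. The pairs that share a number in their titles, 1 with 3 and 2 with 4, were not the most similar. Arrays 1 and 3 were the least similar of all, which argues against the same RNA with dyes exchanged for that pair. Arrays 2 and 4 resembled each other about as much as most other pairs did. A dye effect reached an adjusted p under 0.05 in limma for 0 probes, with 481 at an unadjusted p under 0.05.

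On these arrays ribosomal protein and oxidative phosphorylation genes leaned lower as lists in embryos of high BHB cows, and hypoblast markers leaned higher. The median log2 ratio was -0.34 over 52 ribosomal protein genes (0.79-fold), -0.33 over 74 oxidative phosphorylation genes (0.80-fold) and 0.21 over 14 hypoblast markers (1.16-fold). These 3 of 24 lists passed an adjusted p of 0.05 in camera at its preset correlation of 0.01. With an estimated correlation or with fry 0 passed. The estimated correlation was 0.147 for ribosomal proteins, 0.211 for oxidative phosphorylation and 0.016 for hypoblast markers. Under array signs that are not the real ones, given below, camera also called each of these lists. No single gene passed: limma called 0 of 15038 probes at an adjusted p under 0.05. At an unadjusted p under 0.05 in limma there were 2174 probes, where chance alone gives 752 on average. As probes are not independent, a count by chance can lie far from that average, and no excess is claimed.

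Probe EMBV3_38850 had the smallest adjusted p, 0.067, at a log2 ratio of 3.46 ± 0.65 or 11.02-fold. The other unnamed probes higher by over 6-fold were, in order of fold, EMBV3_05804 (3.11 ± 1.12, 8.63-fold) and EMBV3_07099 (2.62 ± 0.91, 6.15-fold), both with an adjusted p of 0.229. The annotation used here pairs none of the 3 with a gene. They were singled out after their values were seen. All 3 were higher on each of the 4 arrays and above background in both channels. Some or all of them passed the threshold under other settings, which called up to 5 probes, and 2 of them passed without array 1. The smallest adjusted p of any probe in limma ranged from 5.82e-05, with arrays of the same title number averaged, to 0.436 without the pairing within arrays. The averaging takes a reading of the titles that the correlation of arrays 1 and 3 argues against.

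The exploratory threshold was passed by 1244 probes, 485 higher and 759 lower in the high BHB group. Of these 1244, 1067 had 1 direction on all 4 arrays. Over all tested probes 24.3% did, where chance gives 12.5% on average, with a spread that was not estimated. Lower probes made up 61% of the 1244, but 91.5% after median centring in place of loess, 71.2% with the deposited log2 values 76.5% without array 4 and 46.9% under the stricter filter, so that the balance of directions was not settled. Of the tested probes, 363 were not above background in the high BHB channel of any array and 18 in the low BHB channel of any array. With the threshold of median plus 2 MAD, which 1 bright control spot on array 4 does not move, these were 121 and 10. Without the pairing within arrays 746 probes passed. Fitting normexp without the spots set aside removes a fault of the background fit on arrays 1, 2 and 4. With that fit 1826 probes passed, 68% of them lower, and 2 unnamed probes passed the adjusted threshold. The same 3 lists passed, and of the 117 named genes 9 had a value larger by over 1.5 times, 4 a smaller one and 4 the other sign.

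**Figure D1:**
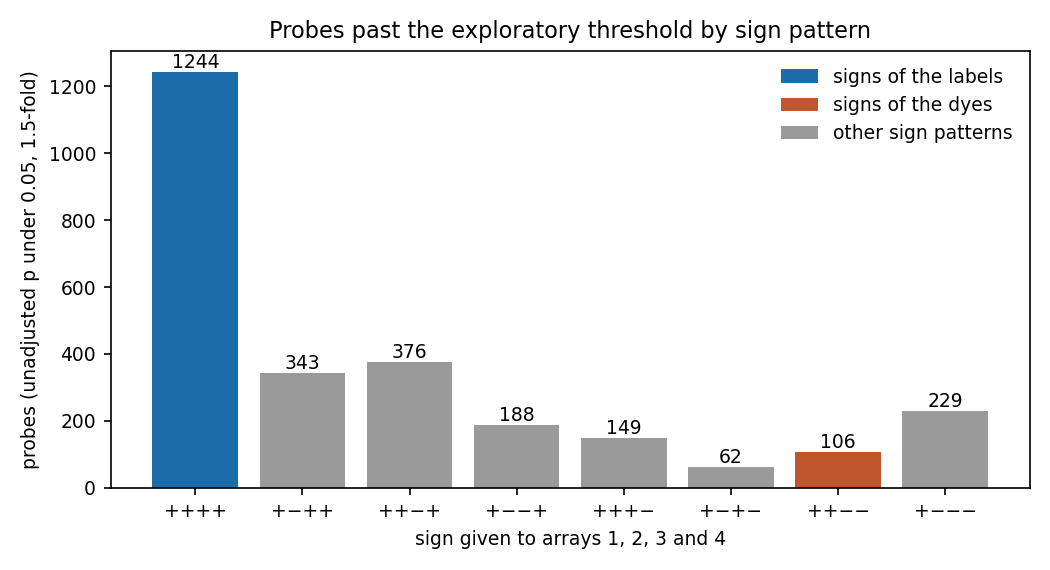
Number of probes past the exploratory threshold for each of the 8 ways of giving signs to the 4 arrays. The real signs gave 1244, the highest of the others 376, and the pattern that follows the dyes 106.

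Among named genes with higher ratios, COL4A1, a chain of basement membrane collagen IV, had the smallest unadjusted p. Its log2 ratio was 1.05 ± 0.08 (2.07-fold, adjusted p = 0.229). FOXP4, a forkhead transcription factor, stood at 1.43 ± 0.43 (2.69-fold) and LY6G6C, a member of the Ly6 family of surface proteins, at 1.24 ± 0.42 (2.36-fold). The other probe of LY6G6C read 0.48. FEM1A, a substrate receptor of a ubiquitin ligase, had 1.11 ± 0.30 (2.16-fold). The transcriptional coregulator ZMIZ2 had 0.99 ± 0.36, TP53I11 0.95 ± 0.35 and the MAP kinase scaffold KSR1 0.90 ± 0.18. GDPD5 followed with 0.87 ± 0.28 (0.39 at its other probe), the RNA-binding protein RAVER1 with 0.85 ± 0.22 and the homeobox gene DLX4 with 0.84 ± 0.26. The acetyltransferase NAA60 had 0.81 ± 0.17, and SDS, which degrades serine, 0.79 ± 0.12. SDS was above background in the low BHB channel on 2 arrays. These 12 genes had adjusted p between 0.229 and 0.232, and none passed. FOXP4 passed in limma under 1 alternative, with arrays of the same title number averaged (adjusted p = 0.0341, range over its alternatives 0.0341 to 0.601). That setting takes a reading of the titles that the correlation of arrays 1 and 3 (r = 0.09) argues against.

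Among named genes with lower ratios, SPDL1, which brings dynein to kinetochores, had the smallest unadjusted p, with a log2 ratio of -1.24 ± 0.23 (0.424-fold, adjusted p = 0.229). The uncharacterised LOC783382 stood at -1.14 ± 0.36 and DERA, a deoxyribose-phosphate aldolase, at -1.10 ± 0.25. TFDP2, a dimerisation partner of E2F factors, had -1.05 ± 0.28. LOC100297121 and ZCCHC17 each had -1.04, with SDs of 0.08 and 0.31, and ATP5MK, a small subunit of ATP synthase, had -1.04 ± 0.26. LOC783459 had -1.03 ± 0.21, EFCAB7 -1.02 ± 0.25 and OTX2, a homeobox transcription factor, -1.01 ± 0.20. EIF3H, a subunit of a translation initiation factor, had -0.97 ± 0.26 and LOC619156 -0.91 ± 0.16. None of these 12 passed, at an adjusted p of 0.229 each. Their ratios were below 0 on all 4 arrays, with array 1 apart from the others for ATP5MK and array 3 for EIF3H.

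**Figure D2:**
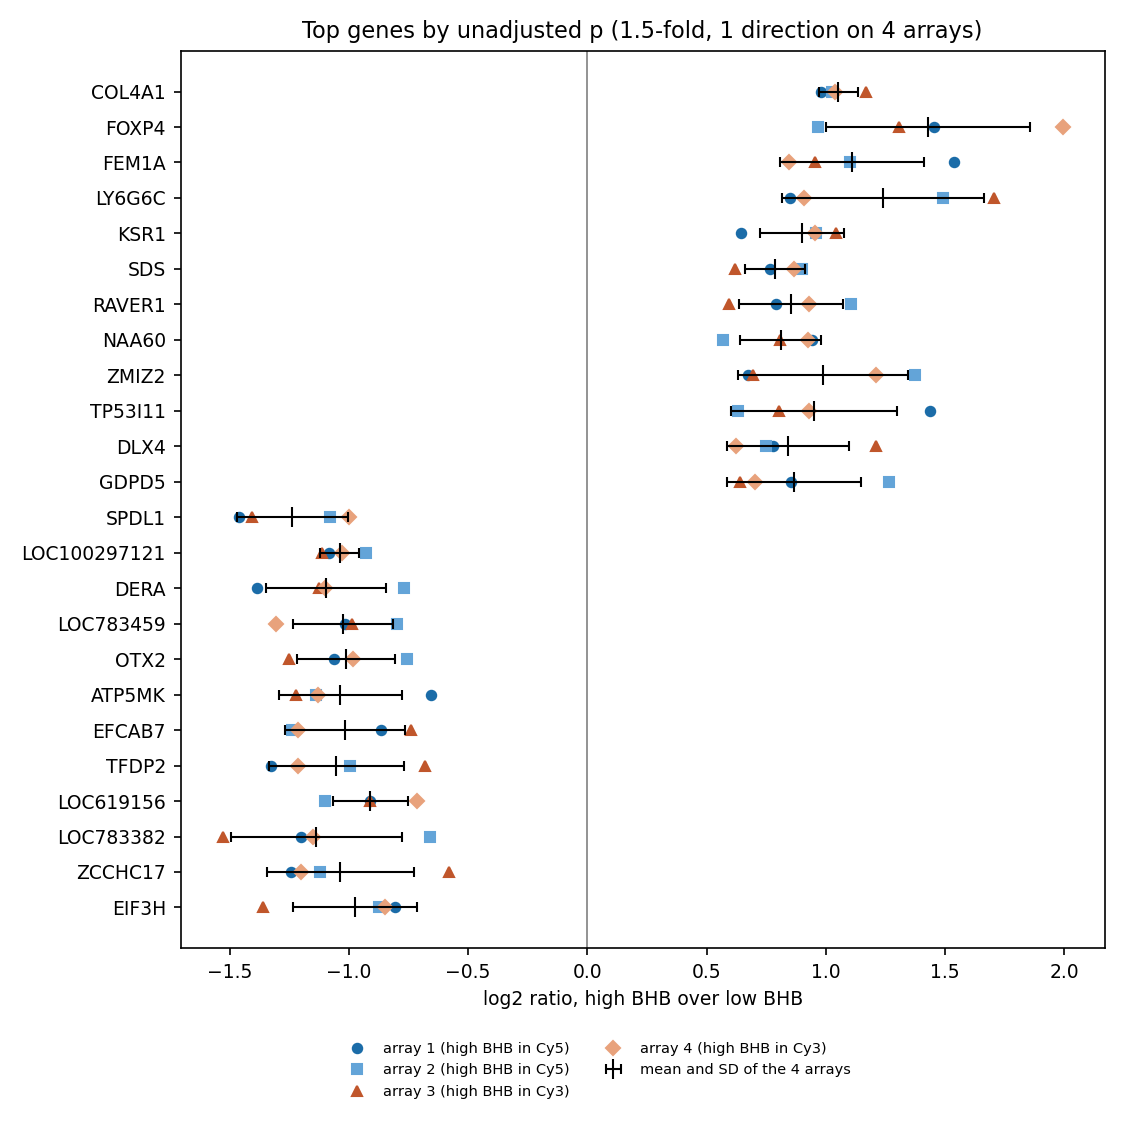
Log2 ratio of high over low BHB (horizontal axis) of the 12 named genes per direction with the smallest unadjusted p among genes of at least 1.5-fold and 1 direction on all 4 arrays. Symbols are single arrays, the black bar is the mean and the whiskers the SD. COL4A1 lies close together at 0.98 to 1.17, while FOXP4 spreads from 0.97 to 1.99, and no gene passed an adjusted p of 0.05.

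Of 52 measured ribosomal protein genes, 49 had ratios below 0 and 3 above. Adjusted over the list alone, 13 fell and 0 rose, and over all probes tested 0 did. RPS3A had the lowest ratio (-1.35 ± 0.82), followed by RPL5 (-1.09 ± 0.63) and RPS7 (-1.07 ± 0.52), parts of the small, large and small ribosomal subunit. The other probe of RPS7 read -0.23. The list's median was below 0 on each array (-0.53, -0.32, -0.18 and -0.60). Camera gave an adjusted p of 9.03e-09, and adjusted p = 0.684 with an estimated correlation. The median became -0.66 when loess was fitted on the tested probes alone.

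Of 74 measured oxidative phosphorylation genes, 57 had ratios below 0 and 17 above. Adjusted over the list alone 9 fell and 0 rose, among them NDUFB1 (-0.93 ± 0.26), and over all probes tested 0 did. The lowest ratios were those of the complex I subunits NDUFV2 (-1.03 ± 1.19) and NDUFC1 (-1.03 ± 0.70), and array 1 stood apart for NDUFV2 at -2.81. The list's array medians were -0.55, -0.18, -0.13 and -0.39. Camera gave an adjusted p of 3.2e-05, and adjusted p = 0.81 with an estimated correlation. Median centring moved the list's median to -0.55.

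Hypoblast markers, genes of the primitive endoderm that lines the blastocyst cavity, had 10 of 14 measured members above 0. Adjusted over the list alone COL4A1 rose and no member fell, and over all probes tested 0 passed. The transcription factor HNF4A had 1.01 ± 1.32 and fibronectin, FN1, 0.71 ± 0.85, each near 0 on arrays 1 and 4. Array medians were 0.14, 0.38, 0.23 and -0.01. Camera gave an adjusted p of 0.031, and adjusted p = 0.684 with an estimated correlation. The call ended with a smaller median after median centring (0.12, adjusted p = 0.056), under the stricter filter (0.13, 0.178) and with loess on the tested probes (0.15, 0.072). It ended with a median as large or larger without array 2 (0.24, 0.098), with the deposited log2 values (0.29, 0.060) and without the pairing within arrays (0.21, 0.059), and the adjusted p ranged from 0.0077 to 0.178 over its alternatives. The median was 0.33 with normexp fitted without the spots set aside.

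**Figure D3:**
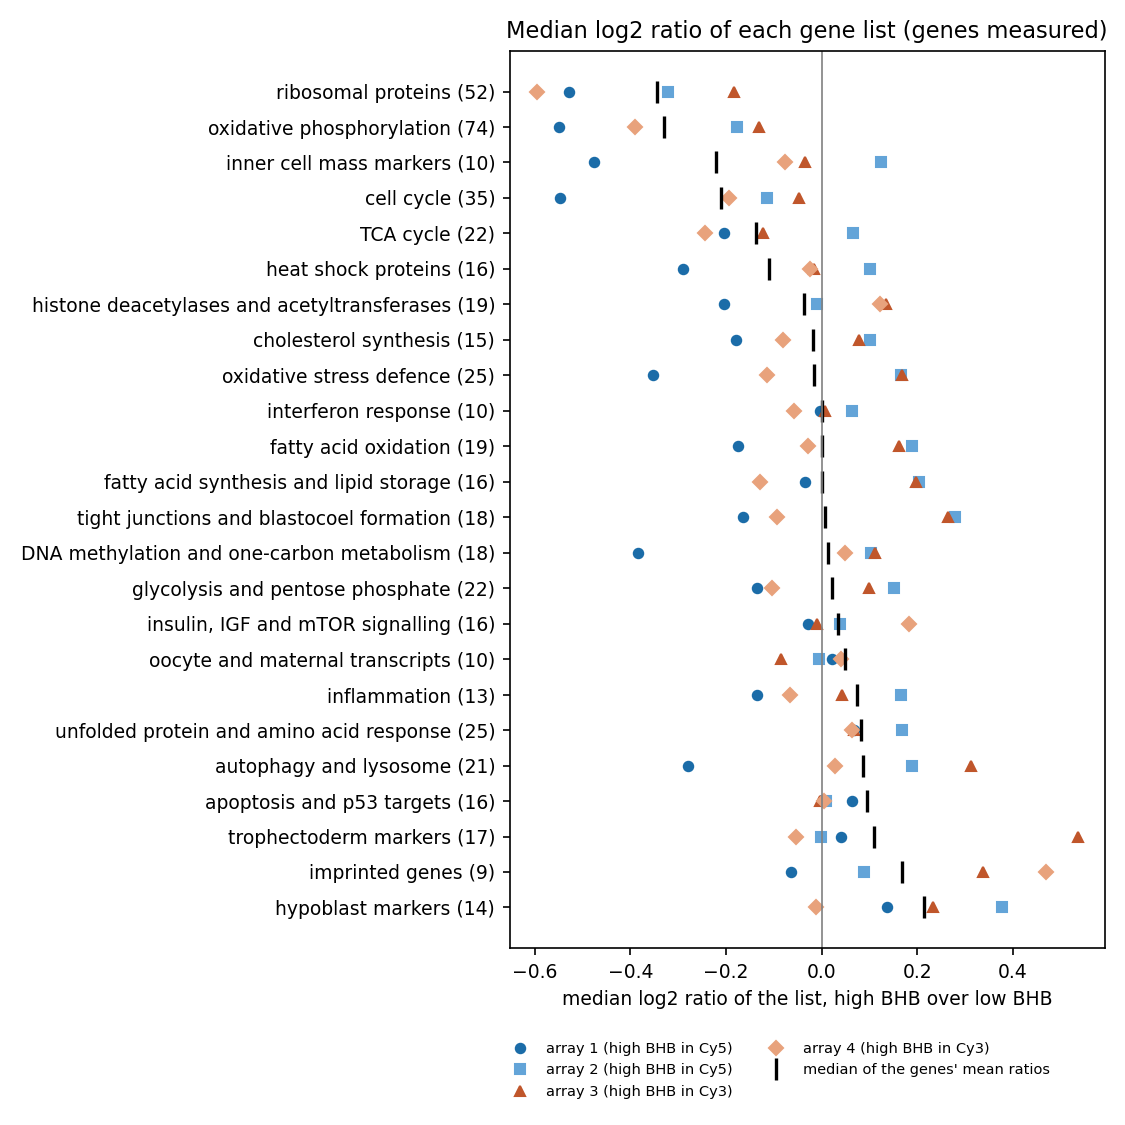
Median log2 ratio of high over low BHB (horizontal axis) of the 24 tested gene lists, with the number of measured genes in brackets. Symbols are single arrays, and the black bar is the median over genes of their mean ratio. Ribosomal proteins and oxidative phosphorylation are below 0 on all 4 arrays, at medians of -0.34 and -0.33, and most other lists have arrays on both sides of 0.

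Leaving out 1 array moved the mean of 61 of the 117 named genes by over 1.5 times or across 0, most often array 1 (45 genes), and none of these genes passed over all probes tested. It moved the median of 27 of the 30 lists as far. The other 3 were ribosomal proteins, oxidative phosphorylation and hypoblast markers. Some bright genes of different lists, named below, were highest on array 1 and next on array 4. Among them were TET3, SHMT1, DDIT4, FADS1, PDK1, CXCL2, AQP3, PTPRC and SPA17. With normexp fitted without the spots set aside TET3 went from 0.62 to 0.43 and FADS1 from 0.82 to 0.59. Over the named genes the median was 1.07 times the value. As this profile was shared, their ratios are not separate evidence for each list. It was picked after seeing the data, and its cause was not tested.

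No other list passed camera's adjusted p of 0.05, and unless stated no member passed adjusted over the list alone. The medians of 17 of the 30 lists took both signs across the alternative settings, all of them lists that did not pass. In several of these lists the median, the mean and camera's direction differed in sign. Camera's direction was up for oxidative stress defence, heat shock proteins and histone modifiers, with median and mean below 0, and up for cholesterol synthesis (median -0.02, mean 0.04). It was up for fatty acid oxidation and for glycolysis, with medians of 0.0013 and 0.02 and means of -0.01 and -0.03, and down for oocyte transcripts (median 0.05, mean -0.08).

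Of the genes that carry or burn ketone bodies, 4 were measured, 3 of them below 0, and the list's median was -0.18. ACAT1, the thiolase that splits acetoacetyl-CoA, had -0.46 ± 0.69 and the monocarboxylate transporter SLC16A1 had -0.36 ± 0.36. ACAT1 was -0.16 without array 1, and SLC16A1 was -0.20 without array 4. SLC16A6 was at 0.0098 ± 0.08, close to background (above it on 3 arrays in the high and 2 in the low BHB channel). BDH1, BDH2, OXCT1 and SLC16A3 had probes that did not pass the filter on dim probes. Fatty acid oxidation had 10 of 19 members above 0 (camera adjusted p = 0.78), with PPARD, a nuclear receptor for fatty acids, at 0.52 ± 0.42, the carnitine transporter SLC22A5 at 0.49 ± 0.89 and HADHB at -0.37 ± 0.59.

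In the TCA cycle list, 17 of 22 members were below 0 (median -0.14, camera adjusted p = 0.479). IDH3A had -0.73 ± 0.67, the pyruvate dehydrogenase subunit PDHB -0.53 ± 0.29 and its inhibitory kinase PDK1 0.72 ± 0.98, whose other probe read -0.13. Glycolysis and pentose phosphate genes had 12 of 22 members above 0 (adjusted p = 0.736). TPI1 stood at -0.93 ± 0.97, LDHB at -0.73 ± 0.54 and hexokinase 1, HK1, at 0.72 ± 0.66. TPI1 was above background in the high BHB channel on 1 array.

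Lipid synthesis and storage genes moved both ways. Of 16 measured members 8 were above 0 (median 0.0018, camera adjusted p = 0.479). Adjusted over the list alone 2 rose, the desaturase FADS2 (0.71 ± 0.15) and ACLY (0.51 ± 0.24), which makes cytosolic acetyl-CoA. In the same list 3 fell, the fatty acid carrier FABP3 (-0.65 ± 0.38), the elongase ELOVL6 (-0.60 ± 0.33) and the lipid droplet protein PLIN2 (-0.52 ± 0.12). ACLY, ELOVL6 and PLIN2 lie outside the naming rule and were named after their values were seen. Over all probes tested 0 passed. FADS1 had 0.82 ± 0.79. Cholesterol synthesis had 9 of 15 members below 0 (adjusted p = 0.788), with its regulators SCAP at 0.73 ± 0.57 and SREBF2 at 0.72 ± 0.78, and CYP51A1 at 0.77 ± 1.18, whose other probe read -0.26.

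Genes of DNA methylation and one-carbon metabolism had 10 of 18 members above 0 (median 0.01, camera adjusted p = 0.558). The demethylating oxygenase TET3 had 0.62 ± 0.82, SHMT1 0.60 ± 0.76 and TDG -0.44 ± 0.46. Without array 1 these were 0.26, 0.28 and -0.27. The methyltransferases DNMT1, DNMT3A and DNMT3B had 0.26 ± 0.23, -0.16 ± 0.45 and -0.30 ± 0.59. DNMT3B was above background on 2 arrays in the high BHB channel. BHB is known to inhibit class I histone deacetylases, an effect on their activity that transcript ratios do not measure. HDAC1 had -0.38 ± 1.24, with array 1 at -2.14 and a mean of 0.21 without it. HDAC2 had -0.04 ± 0.33, with array 4 apart, while HDAC3 and FOXO3 did not pass the filter on dim probes. The list of histone deacetylases and acetyltransferases had 10 of 19 members below 0 (median -0.04, adjusted p = 0.682), among them HAT1 at -0.54 ± 0.08. SIRT6 had 0.44 ± 0.33 and KAT2B 0.41 ± 0.59. All 9 measured imprinted genes were above 0 (median 0.17, adjusted p = 0.0925), with IGF2R at 0.48 ± 0.90, GRB10 at 0.34 ± 0.26, whose other probe read -0.02, and NAP1L5 at 0.22 ± 1.01. The list's median was 0.32 without array 1 and 0.09 without array 4. That list passed without background correction (0.02989) and without array 1 (0.0133), within a range over its alternatives of 0.0133 to 0.594. Camera's adjusted p for it was 0.81 with an estimated correlation.

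Of the unfolded protein and amino acid response, 15 of 25 members were above 0 (median 0.08, camera adjusted p = 0.0925). PSAT1 and ASNS, which make serine and asparagine, had 0.85 ± 0.72 and 0.74 ± 0.36, and DDIT4 0.62 ± 0.77. The list passed without background correction (0.03119) and without array 3 (0.04769), within a range of 0.0312 to 0.327. Its adjusted p in camera was 0.684 with an estimated correlation. Heat shock proteins had 11 of 16 members below 0 (median -0.11, adjusted p = 0.788). Of its members 2 rose adjusted over the list alone, the small heat shock protein HSPB1 (0.81 ± 0.40) and the cochaperone BAG3 (0.72 ± 0.34), and 0 over all probes tested. HSPA8 had -0.65 ± 1.00. Oxidative stress defence had 13 of 25 members below 0 (median -0.02, adjusted p = 0.788), with GSTM1 at 0.64 ± 0.83, SRXN1 at -0.61 ± 0.31 and mitochondrial superoxide dismutase, SOD2, at -0.58 ± 0.40.

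Apoptosis and p53 targets had 9 of 16 members above 0 (median 0.10, camera adjusted p = 0.558), with PERP at 0.65 ± 0.68, the cell cycle inhibitor CDKN1A at 0.56 ± 0.69 and DIABLO at 0.41 ± 1.03. The interferon response was split evenly, with 5 of 10 above 0 (median 0.0011, adjusted p = 0.651). IRF7 had 0.44 ± 0.43, IFI35 0.32 ± 0.21 and B2M -0.21 ± 0.48. Inflammation had 7 of 13 above 0 (median 0.07, adjusted p = 0.607). The cytokine IL6 fell adjusted over the list alone (-0.83 ± 0.19), and 0 members passed over all probes tested. CXCL2 had 0.78 ± 0.73, whose other probe read -0.007, and RELA 0.67 ± 0.69.

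The cell cycle list had 27 of 35 members below 0 (median -0.21, camera adjusted p = 0.087). The spindle checkpoint protein MAD2L1 had -1.03 ± 0.65, cyclin A2, CCNA2, -0.89 ± 0.95 and the replication licensing inhibitor GMNN -0.82 ± 0.77, GMNN with array 1 apart. The list passed after median centring (0.02891), with no filter on dim probes (0.0156) and without array 3 (0.04769), within a range of 0.0156 to 0.209. Its adjusted p in camera was 0.81 with an estimated correlation. Insulin, IGF and mTOR signalling had 10 of 16 members above 0 (median 0.03, adjusted p = 0.558), with RHEB at -0.53 ± 0.61, where array 1 stood apart, and PRKAA1 at 0.48 ± 0.68. Autophagy and lysosome genes had 11 of 21 above 0 (median 0.09, adjusted p = 0.221), with cathepsin D, CTSD, at 0.66 ± 0.19, TFEB at 0.52 ± 0.54 and MAP1LC3A at 0.49 ± 0.34.

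Lineage markers other than hypoblast did not pass. Trophectoderm markers had 11 of 17 members above 0 (median 0.11, camera adjusted p = 0.136), with KRT19 at 0.77 ± 1.29, GATA2 at 0.63 ± 0.21 and KRT7 at 0.51 ± 0.58. CDX2, GATA3, KRT8 and KRT18 had -0.11 ± 0.39, -0.17 ± 0.50, -0.07 ± 0.35 and -0.06 ± 0.59, and each of the 4 changed sign under some alternative. CDX2 was close to background (above it on 2 arrays in the high and 3 in the low BHB channel), so its ratio says little. The KRT8 spot was saturated in the high BHB channel on 1 array, so its ratio is approximate, and its alternatives ran from -0.60 to 0.08. Tight junction and blastocoel genes had 9 of 18 above 0 (median 0.0067, adjusted p = 0.627), with the claudin CLDN4 at 0.88 ± 0.98, the aquaporin AQP3 at 0.73 ± 0.74 and PKP2 at -0.73 ± 0.59. Inner cell mass markers had 8 of 10 members below 0 (median -0.22, adjusted p = 0.556). SPIC fell adjusted over the list alone (-0.67 ± 0.25), and 0 members passed over all probes tested. DPPA3 had -0.67 ± 0.74, NANOG -0.56 ± 1.13, SOX2 -0.25 ± 0.14 and POU5F1 -0.19 ± 0.40. NANOG rested on array 4 (-2.21) and was -0.0096 without it, and POU5F1 was -0.0033 without array 1. SOX17 did not pass the filter on dim probes.

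Oocyte and maternal transcripts had 6 of 10 members above 0 (camera adjusted p = 0.861). ZAR1L fell adjusted over the list alone (-0.65 ± 0.20), and 0 members passed over all probes tested. It was not above background in the high BHB channel on any array. The bound for such a probe equalled its fitted ratio (1.565-fold lower) and so sets no minimum; the log2 ratio was -0.51 with loess on the tested probes and -1.09 with normexp fitted without the spots set aside. The oocyte linker histone H1-8 had 0.48 ± 1.16, with array 1 apart.

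Markers of cells that could accompany the embryos were mostly below the filter, and these lists had too few measured members for camera. Of 24 cumulus and granulosa markers with a probe, 3 were measured, all below 0 (median -0.23): STAR (-0.26 ± 0.21), INHBA (-0.23 ± 0.64) and SERPINE2 (-0.17 ± 0.65). Of 20 endometrial markers 2 were measured, WNT7A (-0.04 ± 0.23) and MSX1 (-0.01 ± 0.03), with a median of -0.03. Both were close to background, above it on 2 and 3 arrays in the high BHB channel. Of 26 leukocyte and blood markers 4 were measured, all above 0 (median 0.18). PTPRC had 0.61 ± 0.63, S100A8 0.22 ± 0.44 and HBA 0.14 ± 0.33. PTPRC shared the profile described above, highest on array 1 and next on array 4. It was 0.40 without array 1 and 0.42 with normexp fitted without the spots set aside. The only measured sperm marker of 14, SPA17, had 0.65 ± 0.68; as its list held no other measured gene, it rose adjusted over the list alone without any adjustment, and did not pass over all probes tested. Without array 1 SPA17 was 0.40, and its other probe read 0.03. Of 5 sex-chromosome markers with a probe XIST alone was measured, at 0.00090 ± 0.17, close to background (above it on 2 arrays in the high and 3 in the low BHB channel). Sexed semen was used, per the labels, and the sex of the embryos was not measured here.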

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

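Among 154 groups of 4 array values examined (named genes, gene lists and array summaries), 10 had 1 array far from the other 3. Chance gives this in about 1 of 20 such groups. Array 1, which had the largest SD of log2 ratios (0.74), was the array apart in 6 of them. No explanation was tested for these values.

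NDUFV2, a complex I subunit, stood at -2.81 on array 1 and between -0.59 and -0.31 on the other arrays. GMNN stood at -1.98 on array 1, against -0.49 to -0.34 elsewhere. RHEB, an activator of mTOR, stood at -1.45 on array 1 and between -0.29 and -0.18 on the rest. The oocyte linker histone H1-8 stood at 2.20 on array 1, against -0.32 to 0.04. ATP5MK was nearest to 0 on array 1 (-0.65) and lay between -1.22 and -1.13 elsewhere. The median of the DNA methylation and one-carbon list was -0.38 on array 1 and 0.05 to 0.11 on the other arrays. EIF3H stood at -1.36 on array 3, against -0.88 to -0.81. The median of the trophectoderm markers was 0.54 on array 3 and between -0.05 and 0.04 elsewhere. HDAC2 stood at 0.45 on array 4, against -0.28 to -0.16. The median of the unfolded protein and amino acid response list was 0.17 on array 2 and 0.064 to 0.067 on the rest.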

How the results depend on the processing

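Loess on the tested probes, the threshold of median plus 2 MAD and normexp fitted without ignored spots (those set aside by the scanner software) were chosen after seeing the data. Ribosomal proteins and oxidative phosphorylation stayed below 0 and past the threshold of camera in all 19 alternatives to the values or the probes, and lost it with an estimated correlation. Among named genes 2045 gene and setting pairs kept direction and side of the threshold, 1 gained it and 40 (in 16 genes) changed sign. Among lists 492 kept both, 7 gained the threshold, 6 (hypoblast markers) lost it, and 63 (in 17 lists) changed sign. Unless stated the cause was not tested. Aquantile left every ratio as it was, and says nothing about stability. The dye effect called 0 probes in all 6 alternatives run. The mean correlation between arrays was 0.25 and ranged from 0.19 to 0.31. Signal over background limits what is seen: 15038 of 43794 probes could be tested, and a stricter filter left 7301.

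Probes past an adjusted p of 0.05 in limma numbered 0, and 1 without background correction, 1 with normexp offset 0 and 3 under the stricter filter. That filter left 7301 probes, to which eBayes was fitted anew, with a smallest adjusted p of 0.00053, so more changed than the number of tests. Probes past the threshold numbered 2 with the series matrix (deposited) values and 5 with title numbers as technical dye swaps. They numbered 3 with trend and robust and 2 with normexp fitted without ignored spots. Without 1 array they numbered 0 to 2. The exploratory count of 1244 was 746 with no replicate block, that is without the pairing within arrays. It was 964 to 1488 without 1 array. The lower share of 61% was 91.5% after median centring, 46.9% under the stricter filter, 71.2% with the series matrix values, 45.5% with title numbers as dye swaps and 76.5% without array 4. The 3 lists past the threshold were 5 without background correction, 0 with an estimated correlation, 0 with fry in place of camera, and 2 to 5 without 1 array (5 without array 3).

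Signs changed as follows, all in results that did not pass the threshold. Without background correction WNT7A was 0.056, HDAC2 0.076, CDX2 0.027, GATA3 0.011, KRT8 0.080 and KRT18 0.022, lipid synthesis and storage -0.00104, histone modifiers 0.033 and endometrial markers 0.0044. With normexp offset 0 fatty acid oxidation was -0.0080. After median centring WNT7A was 0.074, MSX1 0.096, fatty acid oxidation -0.091, glycolysis -0.163, lipid synthesis -0.033, apoptosis -0.038, tight junctions -0.130, trophectoderm -0.018 and endometrial markers 0.085. With no filter ketone body use was 0.0035, fatty acid oxidation -0.012, cholesterol synthesis 0.0013, histone modifiers 0.00053 and endometrial markers 0.000968. Under the stricter filter fatty acid oxidation was -0.019, cholesterol synthesis 0.0013, lipid synthesis -0.011, apoptosis -0.032, tight junctions -0.00041 and oocyte transcripts -0.146. With the series matrix values WNT7A was 0.055, MSX1 0.025, XIST and with it the sex-chromosome list -0.021, HDAC2 0.018, fatty acid oxidation -0.021, glycolysis -0.084, DNA methylation -0.012 and endometrial markers 0.040. With loess on the tested probes WNT7A was 0.024, MSX1 0.038, HDAC2 0.0019, glycolysis -0.0033, cholesterol synthesis 0.024, histone modifiers 0.028 and endometrial markers 0.031. With normexp fitted without ignored spots WNT7A was 0.073, MSX1 0.015, XIST and with it the sex-chromosome list -0.0104, HDAC2 0.00141, glycolysis -0.037, lipid synthesis -0.000953, inflammation -0.00914, tight junctions -0.00519 and endometrial markers 0.044. With the mean of a gene's probes tight junctions were -0.00421.

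Leaving out 1 array at a time gave ranges that cross 0. For genes they were CDX2 -0.21 to 0.081, DIABLO -0.073 to 0.70, DNMT3A -0.31 to 0.015, GATA3 -0.31 to 0.058, H1-8 -0.090 to 0.75, HDAC1 -0.69 to 0.21, HDAC2 -0.20 to 0.043, INHBA -0.45 to 0.029, KRT18 -0.28 to 0.14, KRT8 -0.19 to 0.084, NAP1L5 -0.073 to 0.71, SERPINE2 -0.42 to 0.11, SLC16A6 -0.015 to 0.048, WNT7A -0.10 to 0.070 and XIST (also its list) -0.053 to 0.080. For lists they were DNA methylation -0.075 to 0.075, apoptosis -0.078 to 0.14, autophagy -0.0024 to 0.13, cholesterol synthesis -0.069 to 0.066, endometrial markers -0.056 to 0.035, fatty acid oxidation -0.0027 to 0.030, lipid synthesis -0.014 to 0.10, glycolysis -0.15 to 0.11, histone modifiers -0.065 to 0.097, inflammation -0.028 to 0.13, interferon -0.041 to 0.00257, ketone body use -0.38 to 0.012, oocyte transcripts -0.048 to 0.048, oxidative stress defence -0.13 to 0.075 and tight junctions -0.11 to 0.10.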

Other observations

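Other families of housekeeping genes, picked by the letters of their symbols, chosen after the data were seen and described here for these arrays alone, leaned the same way as the ribosomal proteins. Of 74 measured genes with MRPL or MRPS symbols, nearly all mitochondrial ribosomal proteins, 62 had ratios below 0 in high BHB embryos (median -0.25), among them MRPL44 at -0.92 ± 0.59. Of 20 genes with LSM or SNRP symbols, many of them for proteins of splicing and RNA decay particles, 16 were below 0 (median -0.38), with LSM3 at -0.83 ± 0.19 and SNRPG at -0.82 ± 0.46. Of 43 genes with PSM symbols, mostly of the proteasome, 34 were below 0 (median -0.27), with PSMA3 at -0.78 ± 0.47. They include 7 PSMG, PSMF1 and interacting-protein genes, without which 30 of 36 were below 0, at a median of -0.27. All 9 measured subunits of the CCT chaperonin were below 0 (median -0.36), but on arrays 2, 3 and 4 their medians were -0.02, -0.05 and -0.10. None of the 4 medians changed sign under the 18 settings run, but without array 1 that of the proteasome was -0.13 and that of the chaperonin -0.14. Camera's unadjusted p was 2.05e-05, 8.27e-04, 0.00168 and 0.0401 in this order, and 0.04, 0.0355, 0.317 and 0.216 with an estimated correlation.

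A scan of 66 families of genes that share the letters of their symbols, with at least 10 measured members, was also made after the data were seen. In 7 families camera's adjusted p was under 0.05, and in 0 with an estimated correlation. Besides ribosomal and complex I families, EIF genes, mostly translation initiation factors, were lower (29 of 41 below 0, median -0.28). SLC genes, the solute carriers, were higher on arrays 2, 3 and 4 but not on array 1 (median -0.0086 there), with 80 of 127 above 0 and a median of 0.09. Higher on all 4 arrays were ALDH genes, the aldehyde dehydrogenases (9 of 11 above 0, median 0.11). These medians kept their sign under the 18 settings. Without array 1 that of the EIF genes was -0.12, and under the stricter filter those of SLC and ALDH genes were 0.245 and 0.472.

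The tests of dye bias and of a spot defect, and the sign patterns for the probe counts, were chosen only after the results had been seen. The same holds for asking that the other families also hold with an estimated correlation. The tests on brightness, on other families and on the sign pattern of the lists were written before theirs. The 4 arrays can be given signs in 8 ways, too few for a share under 0.05. For the exploratory count the real signs gave 1244 probes, 1 pattern of the 8 reaching as many, and the highest of the others was 376; the pattern that follows the dyes gave 106. For the adjusted threshold all 8 patterns gave 0. For the gene lists the real signs gave 3 and the highest of the others was also 3, so that 3 of the 8 patterns gave as many. Ribosomal proteins passed camera under 3 of the 7 other patterns and oxidative phosphorylation under 3 of 7, so that with the preset correlation both were also called under signs that are not the real ones. Hypoblast markers passed under 1 of 7.

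The median of the ribosomal protein list was below 0 in both dye orientations, -0.18 on the array nearest to 0. The list was called on its mean over both orientations, in which a dye effect cancels. This check of dye bias thus had little room to fail, and no conclusion is drawn from it. Of 10000 random lists matched on brightness, with a median near 0 (0.04), 0.01% were as low, so the list lay below genes of like brightness. Loess had centred the ratios along brightness on each array, which set random lists near 0 in advance. A bias of bright probes thus cannot be tested in this way. The list's median did depend on the loess fit, at -0.66 with loess on the tested probes. Medians as low were found in under 5% of matched lists for 4 of 4 other families, but such lists take members as independent; with an estimated correlation 2 stayed under 0.05, while the proteasome (p = 0.317) and the chaperonin (p = 0.216, array 1 at -0.77) did not. A loss shared by small, abundant housekeeping transcripts therefore stays open, as transcript size was not measured and these families were dimmer (mean log2 brightness of 10.51 to 11.45, against 13.35). The amount and quality of RNA going into the amplification, the share of morulas against blastocysts and the mother's BHB itself were not tested, and may each be involved.

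For lower oxidative phosphorylation ratios the picture was alike. The list's median was below 0 on all 4 arrays, nearest to 0 at -0.13. As this list was also called on a mean in which a dye effect cancels, no conclusion on dye bias is drawn. Brightness-matched lists had a median of -0.04, with 0.01% of them as low, so the list lay below genes of like brightness. After loess these lists cannot test a bias of bright probes, and they take members as independent. The same untested explanations stay open, and with a correlation estimated within the list camera's p was 0.224.

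The 3 unnamed probes at over 6-fold were above 0 on every array. Their lowest log2 ratio was 1.617, on array 1, above 2 SD of that array's ratios (1.48). They were picked by their mean over both dye orientations, in which a dye effect cancels. This check of dye bias thus had little room to fail, and no conclusion is drawn from it. Each of them lay above 2 SD on 4 of 4 arrays, so their ratios did not rest on 1 array. A spot defect on 1 array would have had to be very large to lift the mean by which they were picked. A difference between the cows or embryos of the 2 groups other than BHB, such as a genetic variant under the probe or at the locus, may account for so large a ratio and stays open, as does BHB; neither was tested, because the probes' sequences were not used here.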
